A study of Caenorhabditis elegans with 2 samples.

How the data were processed

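Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map binding of CEH-82, the product of the homeobox gene ceh-82 (F45C12.2), in first-stage (L1) larvae of Caenorhabditis elegans. The strain, OP212, carried the protein with a GFP-FLAG tag at its C-terminus, and whole animals of both sexes were used as a pool, per the labels. The labels give ceh-82 as the antibody although the tag is GFP-FLAG, so which antibody was used is unclear. They also speak of an insertion while the strain name carries an extrachromosomal array, so which copy was tagged is unclear too. The series held 2 biological replicates, which formed 1 group. Chromatin was fragmented by sonication, per the labels.

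The deposited files were peak lists, given on the ce10 and ce11 genome builds. Per the deposited file descriptions, a relaxed list of peaks and background was made for each replicate against a control alignment and a further relaxed list from both replicates together. An optimal list was then derived from those 3 with the irreproducible discovery rate (IDR), which rates peaks by how well their ranks repeat. Each peak carried a deposited signal value, a deposited score and the offset of its summit. The signal of a peak was the authors' own value on a scale that the labels do not define, and it was used only to rank, describe or select peaks within a list. The deposited score reached a ceiling in many peaks and was not used for ranking. The aligner, the peak caller and the IDR threshold were not given in the sources used here. Read counts were not given either, so the depth of each replicate was unknown, and precision was judged from numbers of peaks and genes.

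The ce11 lists were placed on the WBcel235 assembly, whose 6 nuclear chromosomes contained every ce11 peak, with the Ensembl release 115 annotation. The ce10 lists were compared only with each other, with the end of the last peak taken as the length of a chromosome in the shifts. Positions are given from 1. A gene was called bound when a summit of the optimal list lay within 500 bp of the annotated start of a protein-coding gene, on either side.

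Replicates were compared by taking, from each relaxed list, as many of the strongest peaks as the optimal list held (2346), and counting those of replicate 1 that overlapped any of replicate 2 by at least 1 bp. The null was 1000 circular shifts of replicate 2 along each chromosome (one-sided). Shares of summits near gene starts, in parts of genes and near non-coding genes (within 100 bp) were tested against 1000 circular shifts of the summits (two-sided), whose smallest p is 0.001. The optimal list was compared with relaxed peaks of the pooled data that overlapped no optimal peak by Fisher's exact test, and its strongest with its weakest peaks by a permutation test with 100000 resamples, whose smallest p is 1e-05. Peaks on X were tested by an exact binomial test against the share of gene starts on X. The bound genes of 27 lists (16 of 17 hypodermis markers and every member of the others matched the annotation) were tested by two-sided Fisher's exact tests, and 2080 canonical 6-mers (a 6-mer and its reverse complement counted together) by exact McNemar tests of the 50 bp either side of the summit against flanks 200 to 250 bp away on both sides. Both families were adjusted by the Benjamini-Hochberg method at 0.05. Fisher's tests treat genes as independent, although neighbouring genes can share a peak. Intervals on shares are 95% Wilson intervals and cover counting error only.

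The tests, the gene lists, the preset 6-mers and the alternatives of the processing were fixed before the data were examined, except where a test is said to have been chosen later. The shares of summits in parts of genes, the rank correlation, the GC content and the comparison of X with autosomes at gene starts were added after the data were seen. So was the rule for named items. It took the genes of the 25 strongest peaks with a gene start within 500 bp, ceh-82, up to 4 members per gene list with the strongest peaks, the 5 strongest peaks with no gene start within 500 bp, the 5 6-mers with the smallest adjusted p, and the preset 6-mers TAATTA, GAGAGA, TGATAA and CACGTG. Alternatives changed the distance to gene starts (250 and 1000 bp), the side, the overlap rule, the number of peaks, the build, the background, the assignment of peaks to genes, the distance to non-coding genes (0 and 500 bp) and the 6-mer window (25 and 100 bp). Each replicate was also left out in turn, by using the 2346 strongest peaks of the other.

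The promoter share, the replicate overlap, the gene list tests and the 6-mer tests were tried on simulated data, and the other statistics were not. Of 40 simulated peak sets without a preference for gene starts, 1 was called. A planted overlap of 50% was recovered as 50.5%. All 40 planted gene lists and 3 of 1080 unplanted lists were called. At random positions 0 of 2080 6-mers were called, and a planted 6-mer ranked 1. Random positions lack the difference in GC content that the optimal peaks had between summits and flanks. This trial therefore does not show how many calls base composition gives. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 with random seed 20.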

Results

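Binding of CEH-82 was measured by ChIP-seq in whole L1 larvae that carried the tagged protein. The labels name ceh-82 as the antibody, and whether the antibody recognised the GFP-FLAG tag or CEH-82 itself was not given in the sources used here. ChIP of an untagged strain or of another protein was not analysed here. Signal that does not depend on CEH-82 was therefore not separated in any of the results. The 2 biological replicates each had a relaxed list of 30000 peaks on ce11, the pooled data had 20459 relaxed peaks, and the optimal list held 2346 peaks with a median width of 280 bp. The signal of each peak is the authors' own value from the pooled data and has no replicate error, so the rank of the overlapping peak in each replicate is given in its place. The sequencing depth of the replicates is unknown.

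The first question was whether the replicates found the same sites. The peak upstream of rpl-3, which encodes a protein of the large ribosomal subunit, ranked 1 in both replicates. The peak at cdc-48.1, an AAA ATPase gene, ranked 3 in replicate 1 and 2 in replicate 2, and a peak on X with its summit at 11094214 ranked 2 and 4. Of the 2346 strongest peaks of replicate 1, 1779 overlapped any of the 2346 strongest of replicate 2, a share of 75.8% (95% CI 74.1 to 77.5%). Circular shifts gave 1.29% on average (one-sided permutation p = 0.001, the smallest the shifts can give). The following shares describe the optimal list only and are no independent test of agreement. That list was derived with the IDR from the relaxed lists of these same replicates and of their pooled data. Of the optimal peaks, 85.9% overlapped a top peak of replicate 1, 87.8% of replicate 2, 75.1% of both and 1.45% of neither. All of the 100 strongest optimal peaks overlapped a top peak of both. Across the 2333 optimal peaks matched in both relaxed lists, the ranks had a Spearman correlation of 0.706. This is a correlation across peaks, which are not independent replicates.

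Next, the position of summits relative to genes was examined. Optimal summits were more frequent near the starts of protein-coding genes than shifted summits were. Of the 2346 optimal summits, 1246 were within 500 bp of a gene start, which is 53.1% (CI 51.1 to 55.1%) against 18.4% in shifted summits (central 95% of shifts 16.8 to 20.03%; two-sided permutation p = 0.001, the smallest the shifts can give). The share in the strongest 2346 peaks of replicate 1 alone was 52.6% and of replicate 2 alone 51.8%. With only the 500 bp upstream of starts counted, the share was 49.2% (CI 47.2 to 51.2%) against 9.27% in shifts (permutation p = 0.001). With the starts of all annotated genes except piRNA genes counted, 1654 summits had a start within 500 bp. This share of 70.5% stood against 25.8% in shifts (permutation p = 0.001), in a setting chosen after the data were seen. Peaks called away from gene starts below thus include some near starts of other annotated genes. Of the 1246 summits at protein-coding starts, 90.0% lay upstream of the nearest start, at a median position of -156 bp (interquartile range -255 to -69 bp). The region outside protein-coding genes held 74.1% of all summits against 36.6% in shifts, and 5' UTRs held 4.18% against 1.41%. Coding exons held 0.938% against 24.6%, introns 19.7% against 34.0%, and 3' UTRs 1.07% against 3.399% (adjusted permutation p = 0.001 for each of the 5 locations, from the smallest p the shifts can give).

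Relaxed peaks outside the optimal list served as a background measured in the same way. Of 18044 such peaks, 3923 had a gene start within 500 bp, a share of 21.7% (CI 21.1 to 22.3%). The optimal peaks exceeded this by 31.4 percentage points (odds ratio 4.08, two-sided Fisher's exact p = 3.72e-208). Background summits within 500 bp of a start were upstream in 57.1% of cases, with a median position of -49 bp.

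**Figure D1:**
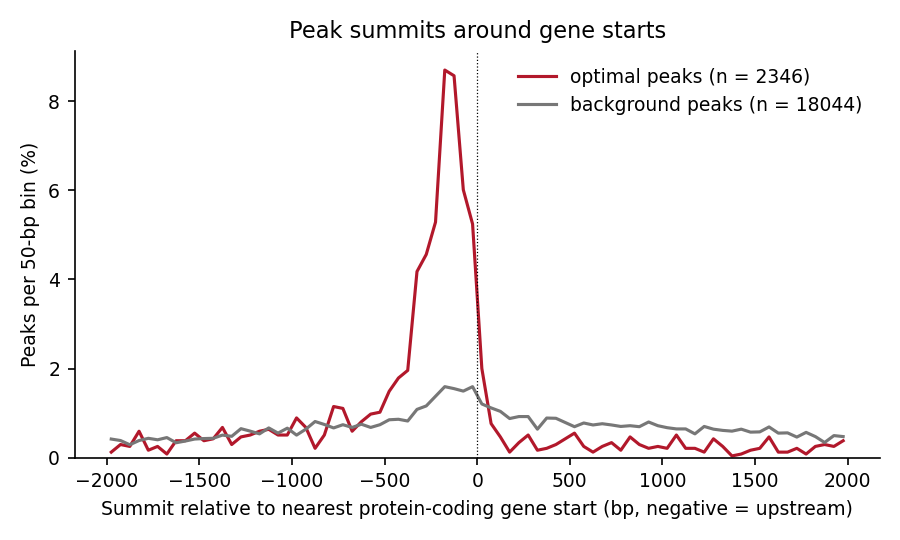
Percent of peaks per 50-bp bin (vertical axis) by the distance in bp of the summit from the nearest protein-coding gene start (horizontal axis), for the 2346 optimal peaks and the 18044 background peaks, each a single pooled list without error bars. The optimal peaks are concentrated upstream of the start, with a median of -156 bp among those within 500 bp, while the background curve is low and broad.

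Strong peaks lay at gene starts more often than weak peaks. Among the 586 peaks with the highest signal, 66.4% (CI 62.5 to 70.1%) had a gene start within 500 bp. Among the 586 with the lowest signal the share was 42.7% (CI 38.7 to 46.7%), a difference of 23.7 percentage points (two-sided permutation p = 1e-05, the smallest 100000 resamples can give).

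The strongest promoter peaks included many at ribosomal protein genes. The 25 strongest peaks with a start within 500 bp covered 36 genes, and all 25 overlapped a top peak of both replicates. Their signal ran from 270 to 619.2, and for 35 of the 36 genes the summit was upstream of the start. The highest was the rpl-3 peak (gene at III, 3867854 to 3869587; summit 3867573, 281 bp upstream; signal 619.2). It was followed by cdc-48.1 (II, 10560036 to 10563407; summit 10563565; signal 552). Ribosomal protein genes among them were also rpl-20, rpl-15, rpl-35, rps-1, rps-12, rps-19 and rpl-12, with signals of 499.04, 484, 440, 398, 348, 328 and 296. Several of these peaks lay between divergent genes, so that rpl-20 shared its peak with Y17G9B.5, rpl-15 with K11H12.8, rps-12 with ska-3, rps-19 with hsr-9 and rpl-12 with lin-54, a gene of the DREAM complex. Genes linked to translation and protein handling were drr-2 (signal 328, shared with the histone methyltransferase gene set-16), iff-2 (307), eif-3.C (293) and sec-61.G (290.0). Chaperonin subunit genes were cct-8 (325, shared with Y55F3AR.2) and cct-1 (306, shared with the Dishevelled homologue mig-5). The protease gene tasp-1 had a signal of 443, the cytochrome c oxidase gene cox-5A 380 and eelo-2 358. The G protein gene egl-30 (306, shared with C53H9.4) and the Pumilio-family gene puf-9 (303) also belonged to this set, the latter on X. The remaining peaks were at cap-2 and gmps-1 (294), C47E8.4 (293), gpap-1 and scpr-1 (284), fbxl-2 (283) and the Integrator subunit gene ints-4 (270), whose summit lay 32 bp downstream of the start in the 5' UTR. The C47E8.4 summit fell in an intron of another protein-coding gene, and the remaining summits of this set lay outside protein-coding genes.

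Gene groups were then compared. The 1246 peaks marked 1633 of 19973 protein-coding genes, 8.18%, and 389 of the peaks had at least 2 starts within 500 bp. Of 27 gene lists, 9 held more bound genes than other genes did (Fisher's exact test, adjusted p under 0.05). Cytosolic ribosomal protein genes stood highest, with 64 of 81 bound (79.0%, odds ratio 44.0, CI 25.3 to 73.2, exact adjusted p = 7.03e-53). This rank depended on the settings. With a distance of 250 bp only 15 of 81 were bound (18.5%, odds ratio 4.08, exact adjusted p = 9.68e-05), a smaller share than for translation factors (35.9%, odds ratio 10.1), proteasome subunits (30.3%), the respiratory chain (27.5%), splicing factors (21.9%) and mitochondrial ribosomal proteins (20%, odds ratio 4.48). The dosage compensation complex also had 20% but did not pass the test. With each peak given only to its nearest start it was 35 of 81 (43.2%, odds ratio 11.8, exact adjusted p = 2.83e-20), below the dosage compensation complex (50%, odds ratio 15.2). In the main setting translation factors had 19 of 39 (odds ratio 10.8, exact adjusted p = 2.49e-10), including iff-2, eif-3.C and the elongation factor genes eef-1A.1 (signal 203) and eef-1A.2 (203). The mitochondrial respiratory chain had 19 of 40 (odds ratio 10.3, exact adjusted p = 3.28e-10), with cox-5A, cox-5B (203), atp-1 (183) and cyc-1 (163) as its strongest. Splicing factors had 14 of 32 (odds ratio 8.80, exact adjusted p = 2.93e-07), led by snr-4 (199.8), rsp-1 and rsp-2, which shared a peak (151), and prp-40 (139). Proteasome subunits had 14 of 33 (odds ratio 8.34, exact adjusted p = 4.03e-07), led by rpn-3 (239), rpn-11 (97.0), pbs-1 (85.7) and rpt-2 (82.8). Chaperones had 20 of 59 (odds ratio 5.82, exact adjusted p = 1.07e-07), with cct-8, cct-1, hsp-110 (239, the peak of rpn-3) and hsp-1 (228) as the strongest. Their share fell to 13.6% (odds ratio 2.80) at 250 bp and to 15.3% (odds ratio 2.74) with each peak at its nearest start. Against only those genes that had a relaxed peak at their start, these lists still passed, with smaller odds ratios. These were 14.2 for cytosolic ribosomal proteins, 4.51 for translation factors and 6.45 for the respiratory chain. Splicing factors had 6.64, proteasome subunits 3.31 and chaperones 3.65.

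The other enriched lists were smaller or less often bound. Mitochondrial ribosomal protein genes had 16 of 70 (odds ratio 3.35, exact adjusted p = 0.000356), with mrps-7 (signal 260), mrpl-28 (167), mrpl-49 (159) and mrpl-45 (118) as the strongest. Vacuolar ATPase subunits had 6 of 20 (odds ratio 4.83, exact adjusted p = 0.00758), among them vha-12 (165), vha-8 (110), vha-15 (105) and vha-1 (85.7). The dosage compensation complex, which lowers X expression in XX animals, had 5 of 10 members bound (odds ratio 11.3, CI 3.45 to 36.8, exact adjusted p = 0.00145), with sdc-2 (77.8), mix-1 (64.8), dpy-30 (57.8) and sdc-1 (45.3) as the strongest. Against only those genes that had a relaxed peak at their start, these 3 lists missed the threshold (exact adjusted p = 0.120, 0.320 and 0.0581). With a distance of 250 bp the vacuolar ATPase (exact adjusted p = 0.411) and dosage compensation (adjusted p = 0.173) lists missed it too.

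Large gene families were bound less often than other genes, in 6 lists, among them receptors, lectins, F-box proteins and neuropeptides. Chemoreceptor genes had 3 of 1302 bound (0.230% against 8.73% of other genes, odds ratio 0.0241, exact adjusted p = 7.37e-44), namely sri-5 (signal 218), srh-16 (143) and srr-10 (67.3). F-box genes had 6 of 322 (odds ratio 0.210, exact adjusted p = 5.65e-06), with fbxb-85 (216), fbxb-88 (56.9), fbxa-37 (44.6) and fbxc-23 (41.1) as the strongest. C-type lectin genes had 3 of 240 (odds ratio 0.141, exact adjusted p = 1.26e-05), which were clec-57 (36.3), clec-126 (35.3) and clec-140 (33.9). Without peaks near tRNA, snoRNA or snRNA genes, only 1 of the 240 was bound (odds ratio 0.0476). Neuropeptide genes had 1 of 140, nlp-4 (39.1), with an odds ratio of 0.0802 and an exact adjusted p of 0.000359. Cuticle collagen genes had 4 of 174 (odds ratio 0.262, exact adjusted p = 0.00412), col-71 (93.9), col-38 (84.0), col-85 (58.9) and col-72 (58.6). Nuclear hormone receptor genes had 9 of 269 (odds ratio 0.385, exact adjusted p = 0.00435), with nhr-47 (149.7), nhr-49 (121), nhr-1 (76.9) and nhr-78 (38.1) as the strongest. Leaving out a replicate moved some of these small counts and ended none of the 6 calls. Without replicate 1, neuropeptides had 0 of 140 and lectins 2 of 240. Without replicate 2, F-box genes had 9 of 322, collagens 6 of 174 and chemoreceptors 2 of 1302. Against genes with a relaxed peak at their start, lectins (23 genes, odds ratio 0.352, exact adjusted p = 0.181) and collagens (33 genes, odds ratio 0.323, adjusted p = 0.0647) missed the threshold. Collagens also missed it in the 1173 strongest peaks (0.226), and nuclear hormone receptors when each peak was given only to its nearest start (0.0924).

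No difference from other genes passed the test for the remaining 12 lists. Homeobox genes had 2 of 91 bound, ceh-38 (signal 113) and ceh-39 (46.9), with an exact adjusted p of 0.0559 that passed at 1000 bp (adjusted p = 0.00897) and against genes with a relaxed peak (0.0334). Histone genes had 9 of 72 (exact adjusted p = 0.287), led by his-37 (224), his-67 and his-68 with a shared peak (79.4), and his-72 (60.8), and passed against genes with a relaxed peak (0.0193). Neuronal markers had 5 of 28 (exact adjusted p = 0.117), with snb-1 (218), egl-21 (70.8), ric-19 (65.8) and ida-1 (57.6), and passed at 1000 bp (0.0315), without replicate 2 (0.0394) and with each peak at its nearest start (0.0486). Cell cycle genes had 3 of 20 (exact adjusted p = 0.304), efl-1 (167), lin-35 (88.0) and cyb-1 (81.2), and passed without replicate 1 (5 of 20, 0.0288) but not without replicate 2 (2 of 20, 0.727). Heterochronic genes had 2 of 11 (exact adjusted p = 0.304), lin-66 (101) and lin-14 (35.6), and insulin pathway genes 2 of 12 (0.321), daf-15 (38.1) and daf-16 (35.0). Both lists passed at 1000 bp (0.0315 and 0.0405), but heterochronic genes had only 1 of 11 without replicate 2 and insulin pathway genes 0 of 12 without replicate 1. Muscle markers had 3 of 30 (exact adjusted p = 0.761), unc-60 (76.2), act-4 (41.6) and act-2 (33.1), bHLH factors 3 of 36 (adjusted p = 1), hlh-11 (105), hlh-30 (39.5) and aha-1 (33.2), and germline markers 1 of 25 (adjusted p = 0.761), spn-4 (68.4). T-box factors (0 of 21, exact adjusted p = 0.482), hypodermis markers (0 of 16, 0.715) and intestine markers (0 of 25, 0.321) had no bound member. Without replicate 2, muscle markers rose to 5 of 30 (exact adjusted p = 0.134) and hypodermis markers had 1 of 16 bound (adjusted p = 1). The peaks at lin-14, daf-15, daf-16, act-2, nlp-4 and clec-140 did not overlap a top peak of both replicates.

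**Figure D2:**
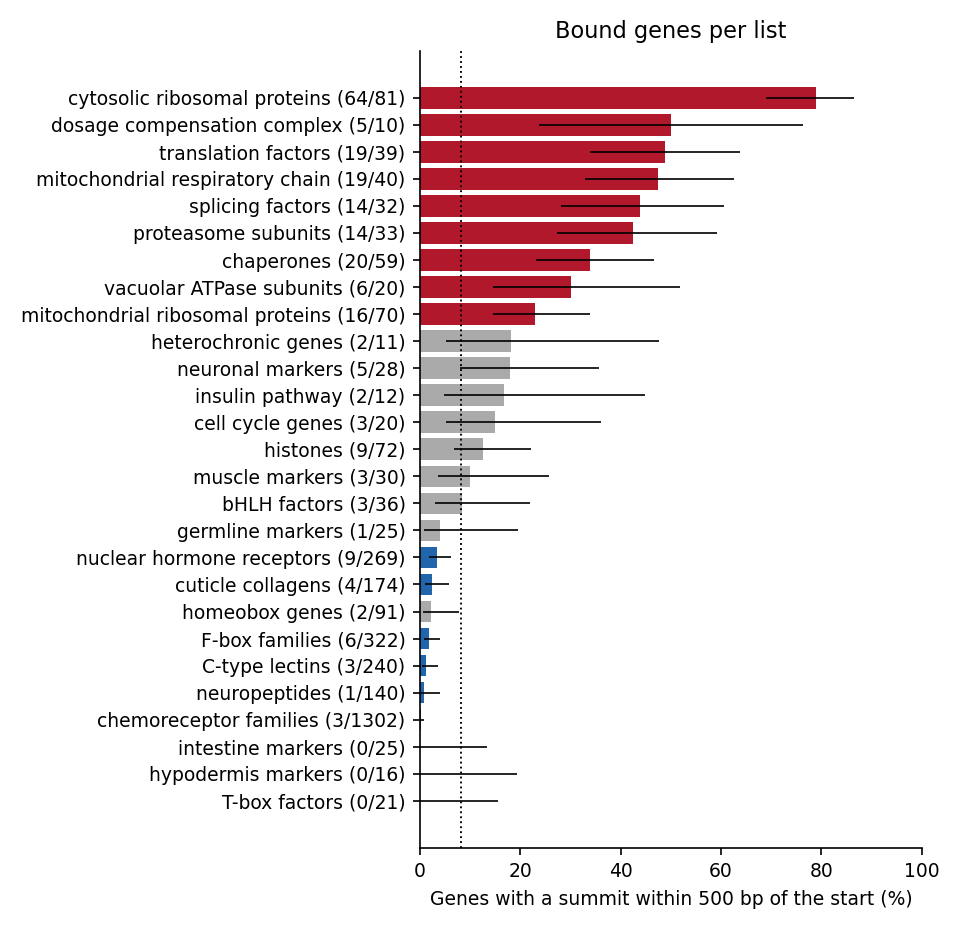
Percent of the genes of each list with an optimal summit within 500 bp of the start (horizontal axis), with 95% Wilson intervals as error bars, and the number bound of the number in the list beside each name. Red bars are the 9 lists bound more often than other genes and blue bars the 6 bound less often at an exact adjusted p under 0.05, grey bars are the other 12, and the dotted line marks the 8.18% of all protein-coding genes.

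The X chromosome differed from the autosomes in where its peaks lay. X held 431 of the 2346 optimal peaks, 18.4% (CI 16.9 to 19.99%), against 13.7% of gene starts (two-sided exact binomial p = 2.08e-10). On X only 33.6% of peaks (CI 29.3 to 38.2%) had a gene start within 500 bp, against 53.5 to 60.8% on the single autosomes and 57.5% on all autosomes together (Fisher's exact p = 3.18e-19). Peaks away from gene starts numbered 286 on X, 26% of all 1100 such peaks, above the 17.7% of chromosome length (exact binomial p = 6.20e-12) and the 18.5% of the length more than 500 bp from gene starts (exact p = 9.18e-10) that X makes up. X held 145 of the 1246 peaks at gene starts, 11.6%, below its share of starts (exact p = 0.0355). These last tests were chosen after the data were seen. Gene starts here are those of protein-coding genes only. Peaks near tRNA, snoRNA or snRNA genes were not left out of the tests on X. How much such peaks add to the share on X was not analysed here. Measured against chromosome length, the total on X was not distinguishable from expectation (exact p = 0.372).

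The 5 strongest peaks with no gene start within 500 bp were all on X and outside protein-coding genes. Their summits were at 11094214 (signal 540), 4209276 (463), 14525919 (418), 806679 (416) and 9465870 (402). The nearest gene starts were those of W02H3.3 (summit 3972 bp downstream), F20B6.9 (-1791 bp, upstream), nspc-17 (-738 bp), gtr-1 (3901 bp downstream) and ZK899.6 (2525 bp downstream). Their ranks ran from 2 to 12 in replicate 1 and from 4 to 17 in replicate 2. Of the 100 strongest optimal peaks 20 were on X, and 16 of those 20 had no gene start within 500 bp.

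**Figure D3:**
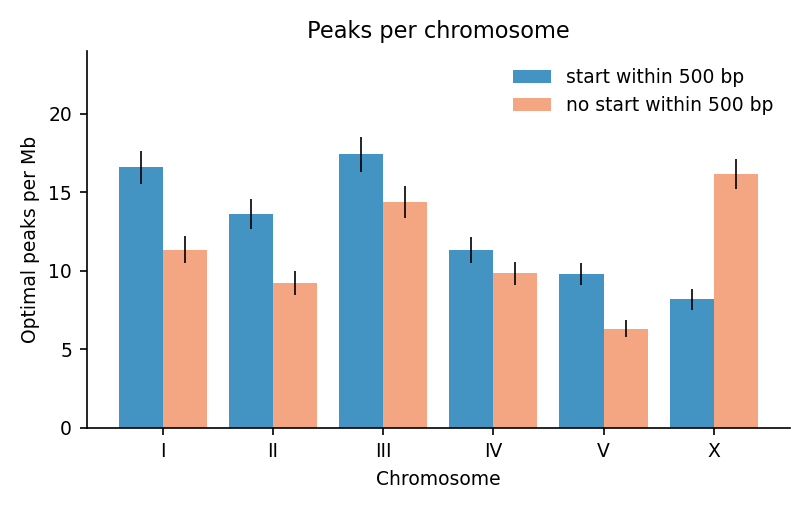
Optimal peaks per Mb (vertical axis) on each chromosome (horizontal axis), split into peaks with and without a protein-coding gene start within 500 bp, with error bars of 1 square root of the count. X is the chromosome with more peaks away from gene starts (16.1 per Mb) than at them (8.18 per Mb), and on every autosome the order is the opposite.

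Peaks were also frequent at small non-coding RNA genes. Within 100 bp of a tRNA gene lay 127 summits, 5.41% (CI 4.57 to 6.404%) against 0.171% in shifts. Genes of snoRNAs, which guide RNA modification, had 74 summits, 3.15% (CI 2.52 to 3.94%) against 0.122%, and genes of snRNAs had 22, 0.938% (CI 0.620 to 1.42%) against 0.0378% (two-sided permutation p = 0.001 for each class, the smallest the shifts can give). In terms of genes, 132 of 612 tRNA genes, 75 of 346 snoRNA genes and 20 of 129 snRNA genes had a summit within 100 bp. The annotation counts genes of spliced leader RNAs, which supply a short leader joined to many mRNAs, as snRNA genes. The 18 spliced leader 2 RNA genes accounted for 8 of the 20 snRNA genes and 10 of the 22 summits. The 99 snRNA genes that are no spliced leader genes had 12 summits, 0.512% (CI 0.293 to 0.892%) against 0.0290% in shifts (permutation p = 0.001, a test chosen after the data were seen). Most summits near tRNA, snoRNA and snRNA genes lay beside the genes and not inside them, and on average so did shifted summits near them. The excess over shifts for tRNA genes was 31.6-fold within 100 bp and 23.2-fold inside. It was 25.8-fold and 7.73-fold for snoRNA genes, and 24.8-fold and 5.73-fold for snRNA genes. Inside the genes themselves lay 28 summits for tRNA (1.19% against 0.0515% in shifts) and 9 for snoRNA (0.384% against 0.0496%; permutation p = 0.001 for both), while the 2 inside snRNA genes (0.0853% against 0.0149%) were not distinguishable from shifts (permutation p = 0.0509). No summit lay near any of the 20 annotated rRNA genes, against 0.0129% in shifts (permutation p = 1), a number too small to test. Of the background peaks 0.870% were near tRNA genes and 0.211% near snoRNA genes.

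Sequences at the summits were rich in GAGA repeats and in overlapping 6-mers around GACGCA. Of 2080 canonical 6-mers, 718 were more frequent within 50 bp of the summit than in the flanks and 577 were less frequent (exact McNemar test, adjusted p under 0.05). The leading ones depended on the peaks used, and among summits with a gene start within 500 bp they were ACGCGC, GCGCAC and GAGCGC. GACGCA, with the smallest p over all summits, occurred at 21.8% of summits (CI 20.2 to 23.5%) and in 2.51% of flanks (CI 1.95 to 3.23%; exact adjusted p = 7.2e-95). CGTCTC occurred at 24.5% against 4.01% (exact adjusted p = 2.34e-89) and ACGCAG at 21.4% against 2.60% (adjusted p = 3.03e-89). The other leading 6-mers were scarcer at summits, AAAATT with 16.4% against 43.8% (exact adjusted p = 9.18e-91) and AAAAAT with 23.6% against 51.9% (adjusted p = 1.32e-89). Among the preset 6-mers, GAGAGA was at 31.5% of summits and in 9.63% of flanks (exact adjusted p = 4.65e-77), and the E-box CACGTG at 3.41% against 1.62% (adjusted p = 0.000276). The homeodomain core TAATTA was at 1.19% of summits (CI 0.827 to 1.72%) and in 6.05% of flanks (CI 5.16 to 7.09%; exact adjusted p = 1.01e-18), and the GATA site TGATAA at 2.05% against 10.1% (adjusted p = 2.48e-30). The GC content was 48.4% within 50 bp of summits and 35.5% in the flanks. The 6-mer tests did not allow for this difference. The calls, those of CACGTG and TGATAA among them, were therefore not separated from base composition.

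**Figure D4:**
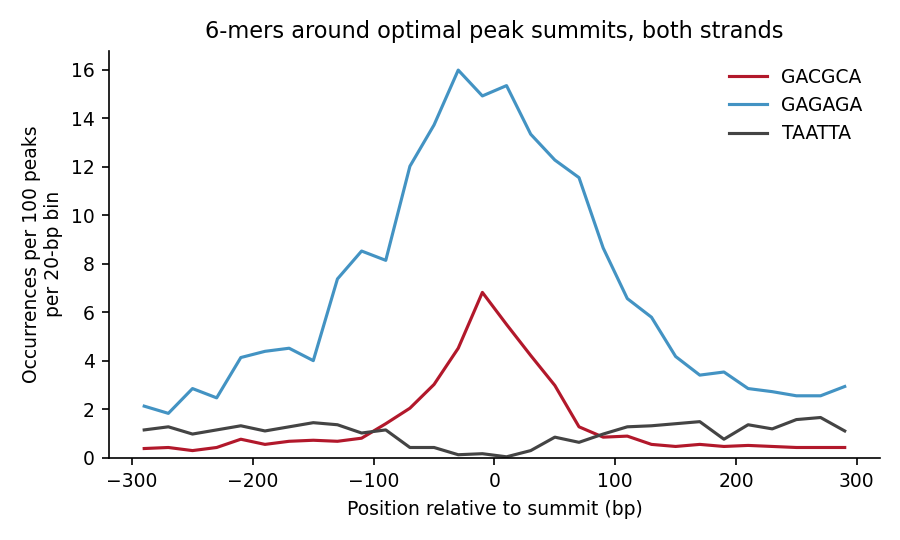
Occurrences of 3 of the named 6-mers on either strand per 100 optimal peaks in 20-bp bins (vertical axis) by position in bp from the summit (horizontal axis), over 2346 peaks without error bars. GACGCA and GAGAGA rise towards the summit and TAATTA falls there, from 1.15 in the bin starting at -300 bp to 0.0426 in the bin starting at 0 bp.

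The tagged gene itself was not a peak. No optimal summit lay within 20 kb, or within 50 kb, of the start of ceh-82 (WBGene00018433; II, 1732232 to 1733291, plus strand), and 43.7% of protein-coding gene starts likewise had none within 20 kb. The nearest optimal summit was at 1820102, 87870 bp away, with a signal of 33.4. The pooled relaxed list had 3 summits within 20 kb of ceh-82, against a median of 8 over all gene starts.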

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

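Most results kept their direction and their side of the threshold. The 6 comparisons with a test were recomputed under 39 alternative settings, and 37 of these kept the direction and the side of the threshold. The exceptions concerned peaks on X: 18.4% was not distinguishable from the share of X in chromosome length, and among peaks within 500 bp of a gene start, an alternative chosen after seeing the data, the direction turned to 11.6%. Cytosolic ribosomal protein genes stayed enriched throughout, but the share bound fell from 79.0% to 18.5% at 250 bp and to 43.2% with each peak at its nearest start. The counts of lists and 6-mers stayed within 1.5 times the main count in 24 of 24 alternatives, which does not mean the same lists. Enriched lists ranged from 7 to 12 against 9 and depleted lists from 5 to 7 against 6. Against genes with a relaxed peak 6 of the 9 and 4 of the 6 were shared. For snoRNA and snRNA genes 10 of 11 alternatives kept the verdict, and the other did not, since summits inside snRNA genes (0.0853%) were not distinguishable from shifts (permutation p = 0.0509). The replicate overlap ranged from 56.6% (4692 peaks per replicate) to 78.5% (1173 peaks). Leaving out a replicate gave promoter shares of 51.8 to 52.6% and 10 enriched lists each way. The other settings added after seeing the data (autosomes only, all gene starts except those of piRNA genes, no peaks near tRNA, snoRNA or snRNA genes, snRNA genes without spliced leader genes, 1 or 3 mismatches in the 12-base element) kept every verdict for the promoter share, its dependence on strength, the counts of 6-mers and lists, snRNA genes and the element. Peaks near tRNA, snoRNA or snRNA genes were left out for the gene lists only. Lists without a called difference changed direction as follows, by percent of members bound. Muscle markers turned at 250 bp (3.33%), in the 1173 strongest peaks (3.33%) and against genes with a relaxed peak (18.8%). The bHLH factors turned at 1000 bp (8.33%), in the strongest peaks (2.78%), against genes with a relaxed peak (27.3%) and with each peak at its nearest start (5.56%). Insulin pathway genes turned to 0% in the strongest peaks and to 0% without replicate 1 (16.7% without replicate 2), and germline markers to 50% against genes with a relaxed peak. The cause was not tested for any of these. Lists with few bound members also moved when a replicate was left out, such as cell cycle genes (25% without replicate 1, 10% without replicate 2), muscle markers (16.7% without replicate 2) and heterochronic genes (9.09% without replicate 2). For named genes, 460 of 530 alternative values kept a summit and 70 did not. No paired analysis was possible because the design has 1 group. Depth is unknown, so whether weak peaks are limited by reads is not analysed here.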

Other observations

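All tests in this part were chosen after the data were seen, except the count of peaks around the tagged gene. Gene families named by a shared symbol prefix with at least 10 members were also tested. Of 175 families, 17 were bound more often and 11 less often than other genes (two-sided Fisher's exact test, adjusted p under 0.05). Many of them, such as rpl, rps, str and clec, belong to the lists already given. The families named next do not. Genes of the secretory pathway (prefix sec) had 10 of 19 bound (odds ratio 12.5, exact adjusted p = 2.11e-05) and nuclear pore genes (npp) 11 of 26 (odds ratio 8.29, adjusted p = 6.43e-05). Vacuolar sorting genes (vps) had 9 of 31 (exact adjusted p = 0.00717), Integrator genes (ints) 5 of 11 (adjusted p = 0.0119) and cyclophilin genes (cyn) 6 of 16 (adjusted p = 0.0119). Glucuronosyltransferase genes (ugt) had 0 of 67 bound (exact adjusted p = 0.0387).

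Spliced leader 2 RNA genes, whose product is joined to downstream mRNAs of operons and which are among the snRNA genes already counted, had a summit within 100 bp in 8 of 18 cases, and 10 summits in all, 0.426% against 0.00605% in shifts (adjusted permutation p = 0.002, from the smallest p that 1000 shifts can give). None of the 12 spliced leader 1 RNA genes had a summit, against 0.00269% in shifts, a number too small to test. Whether reads could be placed uniquely at these genes was not examined. Spliced leader 1 and 2 RNA genes were not tested against each other. Summits near miRNA genes, 0.128% against 0.0719% (adjusted permutation p = 0.526), were not distinguishable from shifts. Pseudogenes had fewer summits than in shifts, 0.426% against 3.32%, and piRNA genes too, 0.384% against 2.03% (adjusted permutation p = 0.002 for both). The 10-mer with the largest excess of summits over flanks was GAGACGCAGA, at 258 summits (11.0%) and in 11 flanks (0.469%). It occurred at 16.2% of the 814 autosomal summits away from gene starts, 5.94% of the 286 on X and 8.75% of the summits at gene starts.

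The strong X peaks away from gene starts raised the hypothesis that they mark recruitment elements of the dosage compensation complex, known for the 12-base consensus TCGCGCAGGGAG. With at most 2 mismatches, the element lay within 100 bp of 22 of the 286 X summits away from gene starts, 7.69% (CI 5.13 to 11.4%), against 10 of 814 autosomal ones, 1.23% (Fisher's exact p = 3.24e-07), and of 14 of the 20 strongest on X against 0 of the 20 strongest on autosomes; the strongest of all held it without a mismatch (X, 11094123 to 11094134, minus strand). X peaks at gene starts held it in 4.83% of cases, which over all peaks was not distinguishable from those away from starts (Fisher's exact p = 0.313), but in only 1 of their 20 strongest. With at most 1 mismatch it was at 4.20% of the X summits and 0% of the autosomal ones (Fisher's exact p = 8.02e-08), and with at most 3 at 24.1% and 15.97% (exact p = 0.00311). Among the 20 strongest of each group, at most 3 mismatches gave 17 on X and 5 on autosomes away from gene starts, and 5 on X at gene starts. The fifth strongest X peak away from gene starts, with its summit at 9465870, had 3 mismatches and counts as lacking the element in what follows. The element may account for the strongest X peaks. Peaks that matched it with at most 2 mismatches did not make up the whole X excess. X still held 24.7% of the 1068 peaks away from gene starts that lacked it. X makes up 17.7% of chromosome length (exact binomial p = 8.45e-09) and 18.5% of the length more than 500 bp from gene starts (exact p = 4.23e-07). With at most 1 and at most 3 mismatches the share was 25.18% and 24.1%, against chromosome length (exact binomial p = 6.09e-10 and 1.17e-06). Recruitment sites that the match misses would count as lacking the element. The test therefore cannot decide whether such sites account for the rest of the X excess. Peaks near tRNA, snoRNA or snRNA genes were not left out of it either. Higher coverage of the whole X was not measured. X held 11.6% of peaks at gene starts, below its 13.7% of gene starts (exact binomial p = 0.0355). That share also depends on which genes are bound, so it cannot decide whether coverage of X was higher.

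The shortage of the homeodomain core at summits was weighed against the base composition of summits. The summit to flank ratio of TAATTA was 0.197 (CI 0.131 to 0.296), and the 35 other 6-mers made of A and T only were all scarcer at summits, with a median ratio of 0.344 and a central 95% range of 0.209 to 0.497. The ratio lay below that range while its interval reached into it, so a specific lack of the core cannot be told apart from the low A and T content. TAATTA was the only homeodomain sequence among the preset 6-mers. The sequence that CEH-82 itself prefers was not determined here. Signal at active promoters whatever the tagged protein also stays open: it needs no core, which was at 1.19% of summits, and ChIP of an untagged strain or of another protein was not analysed here. The same limit holds for the results on gene lists, non-coding RNA genes and X.

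Copies of the tagged gene on the extrachromosomal array, which the strain name points to, could give peaks around ceh-82. The count was 0 optimal summits within 20 kb, where the 95th percentile over all gene starts is 3, which argues against array copies as a source of peaks in the optimal list. A control alignment from the same strain would remove such signal, and the strain of the control was not given in the sources used here.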
